A study of Mus musculus with 6 samples.

How the data were processed

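Ovaries of mice at postnatal day 14 were profiled by RNA sequencing. Each of the 6 libraries was made from a pool of 3 ovaries, 1 from each of 3 mice, with the same amount of total RNA per pool, per the labels' protocols. The control group held 3 pools of mice homozygous for a floxed allele and without Cre. The conditional knockout group, called cKO here, held 3 pools of mice homozygous for the floxed allele and carrying Gdf9-iCre. Gdf9-iCre is a Cre recombinase driven by the promoter of an oocyte gene. Groups were taken from the genotype label. The replicate numbers follow the order of deposit and only name the libraries. All 6 libraries were run in lane 6 of an Illumina HiSeq, per the labels.

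The deposited table held FPKM (fragments scaled to transcript length and to the library's mapped fragments) for 37924 Ensembl genes in the 6 libraries. TopHat2 2.0, Cufflinks 2.0 and the genome build mm10 are named in the submitters' processing notes, with no role or order. The annotation, the strand setting, the filters and any scaling between libraries are not given in the sources used here. Reads were not used here, so a count model was not fitted. FPKM divides by the library total, so a rise of abundant transcripts lowers the values of all other genes. Genes that overlap on opposite strands, and members of gene families with near-identical sequence, can share fragments in such values.

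The depth of each library was estimated from low FPKM values below 0.15, each read as 1 fragment. The median was taken around the most frequent estimate, where 188 to 243 of the 722 to 834 low genes per library lay. Genes with 1 transcript and at least 1500 bases of exon were used, with 150 bases taken off the length for the fragment. The estimates were 22.7, 21.6 and 19.6 M fragments (M for 1e6) for control 1 to 3 and 23.3, 22.5 and 24.9 M for cKO 1 to 3. An FPKM of 1 in a gene of 2 kb then stands for 39.2 to 49.8 fragments, depending on the library. These depths are estimates, and no interval was built on them.

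Gene coordinates, biotypes and exon overlaps were taken from GENCODE M21, whose assembly is that of mm10. Of the 14934 genes tested, 14740 were found there by Ensembl identifier. Coordinates are 1-based.

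The comparison of cKO with control was made with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1). Genes entered with a mean FPKM of at least 0.5 over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p below 0.05 counted as passing. Fold changes are cKO over control on the log2(FPKM + 1) scale, which understates the change of low genes. The verbs rose, fell and changed are used of genes that passed this test. The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined.

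For 25 fixed gene lists with 541 members, 533 members were found in the table and 471 were tested. Each list was tested against all other genes with limma's camera at its preset correlation of 0.01, and again with a correlation estimated from the libraries. The rotation test fry tested whether the members of a list moved in 1 direction on balance. Adjustment was over the 25 lists. The number of passing members was counted over all genes tested and also adjusted over the list alone. The mean log2 value of each list per library was compared by an exact permutation test, two-sided, whose smallest p with 3 libraries against 3 is 0.1.

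Named genes were Gdf9, the 10 largest increases and the 10 largest decreases among passing genes whose groups did not overlap and whose higher group had a mean FPKM of at least 1. Gene model names were left out, and so were clone-based names and small RNAs, a reading of the rule made after the data were seen. From each list came up to 4 passing members with the smallest p, or the 2 members with the highest mean where none passed. Results of some genes are not reported here. Other genes are named where the text says that they were chosen after their values were seen.

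The procedure was tested on simulated data of 14934 genes for the comparison of cKO with control. Noise was normal and independent between genes and libraries, with the SDs of the limma fit itself. Changed genes were drawn from those with a mean above 2 on the log2 scale. The simulation therefore checks the procedure under its own assumptions and does not measure power or error in the real libraries. It recovered 96% of 100 genes changed by 1 on the log2 scale and 100% of 100 genes changed by 2. Of 217 genes called, 11 (5.07%) had been left unchanged. The 1 shifted list was called, and so was 1 other list.

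Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 2, quantile normalisation, centring on the median or on a list of reference genes, array weights, robust eBayes, a minimum log2 change of 1, and leaving out each library in turn. After the data were seen, 4 more were added: removal of the trends with GC content and exon length, rescaling on protein-coding nuclear genes, leaving out control 3 and cKO 3 together, and the 3 controls against cKO 1 alone. Count tests planned for the case of counts or recovered reads were not run, since the table held FPKM and the transcript lengths behind its values are not given in the sources used here. The authors' own test results were not analysed here. All 10 splits of the 6 libraries into 3 and 3 were refitted. Scripts were run with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.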

Results

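Transcript levels were measured in 6 pooled ovary libraries from mice at postnatal day 14, when the ovary holds growing follicles. The 3 control libraries came from mice homozygous for a floxed allele. The 3 cKO libraries came from mice homozygous for the same allele with Gdf9-iCre, in which the floxed gene is deleted in oocytes. The comparison asks which ovarian transcripts differ after this deletion. Each library pooled 1 ovary from each of 3 mice, so the spread between libraries is a spread between pools of animals. The estimated depth was 19.6 to 24.9 M fragments per library (M for 1e6). Between 13170 and 13649 genes had an FPKM of at least 1. The share of summed FPKM from mitochondrial genes was 11.9%, 13.8% and 14.2% in control 1 to 3 and 7.31%, 13.9% and 10.7% in cKO 1 to 3. Values below are mean FPKM ± SD over 3 libraries per group, and adjusted p-values are from limma.

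Gdf9, the oocyte growth factor gene whose promoter drives the Cre, did not pass the test. It measured 221 ± 21.2 FPKM in control and 267 ± 72.7 FPKM in cKO (SD, n = 3), with a log2 change of 0.24, a standard error of 0.19 and an adjusted p of 0.476. Sumo2, a SUMO modifier gene, measured 365 ± 13.0 FPKM in control and 310 ± 19.7 FPKM in cKO, at an adjusted p of 0.132. The SUMO pathway list had an adjusted p of 0.982 by camera. Whole ovary contains many cells in which Gdf9-iCre is not active, and the genotype labels were not checked from the values.

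In cKO ovaries 334 genes rose and 312 fell out of 14934 tested. Those that fell included 10 of 28 measured granulosa cell genes and 7 of 23 proliferation genes. Those that rose included the egg coat genes Zp2 and Zp3 and the oocyte transcription factor genes Sohlh1 and Figla. Of the passing genes, 39 rose and 66 fell by at least 1 on the log2 scale. At an unadjusted p below 0.05, 2167 genes were higher and 1463 lower. The groups did not overlap for 4480 tested genes, 30% of them against 10% by chance. The counts varied with the library left out. Without control 1, 1 gene rose and 4 fell, and 0 rose and 2 fell without control 2 or without cKO 1. Without cKO 2, 40 rose and 38 fell. Without cKO 3 there were 209 and 176, and without control 3 there were 307 and 353. The number of genes at an unadjusted p below 0.05 stayed between 2266 and 3633 in these fits. The split between higher and lower genes also moved with scaling, from 254 against 577 with libraries centred on the median to 437 against 251 with libraries centred on the reference genes.

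**Figure D1:**
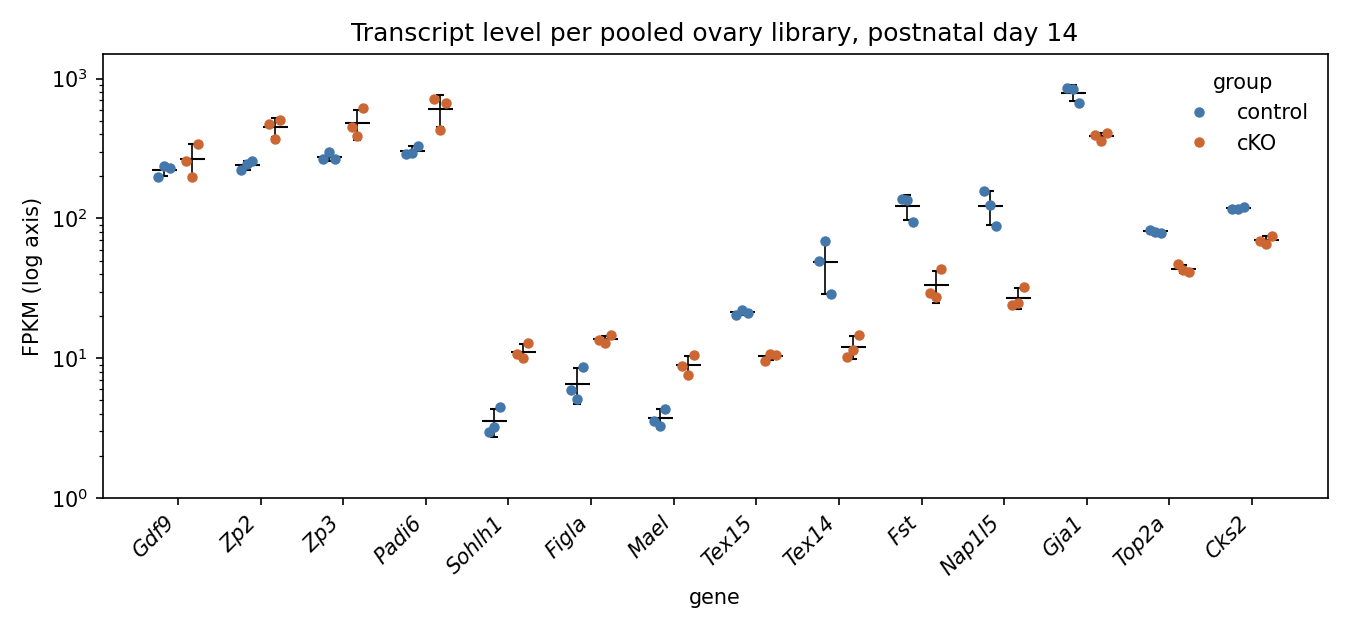
FPKM (log axis) of 14 named genes in each of the 6 pooled libraries; points are single libraries in the order 1 to 3, horizontal marks are group means and bars are SD over 3 libraries. Gdf9 overlaps between control (blue) and cKO (orange), while Fst lies between 94.1 and 137 FPKM in control and between 27.6 and 43.3 FPKM in cKO.

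Libraries were not equally far apart. Pearson correlations of log2 values ran from 0.9907 to 0.9957 within groups and reached 0.9904 between groups. On a control to cKO axis built without the library placed on it, a measure chosen after the data were seen, control 1 and control 2 lay at -0.043 and -0.061. Control 3 lay at 0.411, and cKO 1, cKO 2 and cKO 3 at 0.997, 0.813 and 0.649. With control 3 and cKO 3 both left out, 204 genes rose and 267 fell. The numbers in the labels fall into 2 ranges, 1 with the 3 controls and cKO 1 and the other with cKO 2 and cKO 3, and what they stand for is not stated. Within the first range, the 3 controls against cKO 1 gave 22 higher genes and 1 lower gene, with the lone cKO library assumed to vary as the controls did; the second range holds cKO libraries only.

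**Figure D2:**
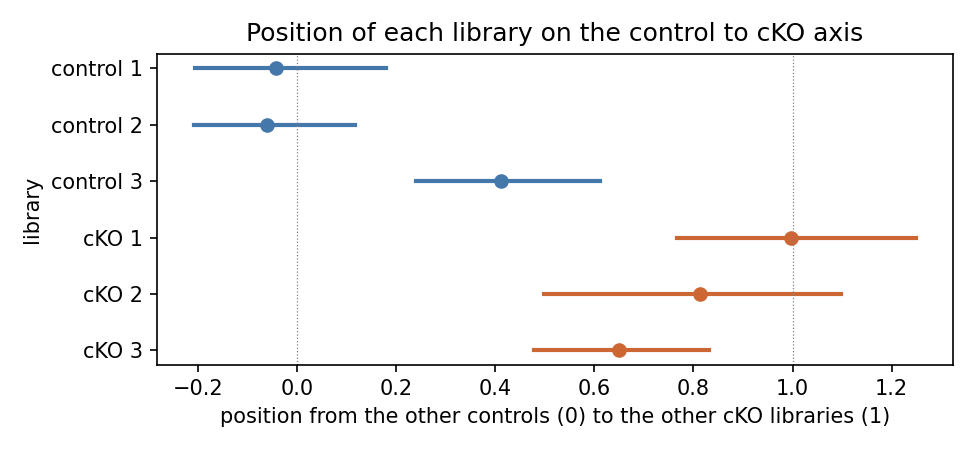
Median position of each library over 500 genes on the axis from the mean of the other controls (0) to the mean of the other cKO libraries (1); lines span the quartiles over genes. Control 3 lies at 0.411, between control 2 at -0.061 and cKO 3 at 0.649.

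The 10 largest decreases among genes that the naming rule admits were led by Slc38a5, an amino acid transporter gene, which fell from 54.8 ± 26.8 to 8.41 ± 2.18 FPKM (SD, n = 3; log2 change -2.44, standard error 0.40, adjusted p 0.028). Fam183b fell from 9.34 ± 1.32 to 0.99 ± 0.18 FPKM, a log2 change of -2.37 with a standard error of 0.13 and an adjusted p of 0.0012. Dnajb13, a gene of cilia and sperm tails, fell by 2.42 on the log2 scale, and Tex14, needed for germ cell bridges, fell by 1.86 with a standard error of 0.29, from a mean of 49.0 to one of 12.1 FPKM. Nap1l5, Rasl10a, Slc6a15, Mpped2, Fst and Apoa4 completed the 10, with log2 changes from -2.13 to -1.84. Dnajb13, Rasl10a, Fst and Apoa4 share exon sequence with genes on the opposite strand, so their values may include fragments of those genes. All 10 had their lowest control value in control 3; Slc38a5 and Tex14 were there at 23.9 and 28.8 FPKM, against at least 67.4 and 49.3 FPKM in the other controls.

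Among genes that the naming rule admits, the largest increases were led by genes of mast cell granules. The tryptase gene Tpsab1 rose from 4.07 ± 1.24 to 13.5 ± 4.28 FPKM (SD, n = 3; adjusted p 0.0278). The mast cell protease genes Mcpt4 and Cpa3 and the second tryptase gene Tpsb2 rose by 1.48, 1.44 and 1.36 on the log2 scale. Tpsab1 and Tpsb2 are close paralogs on chromosome 17 and can share fragments. Sohlh1, a transcription factor gene of early oocytes, rose from 3.56 ± 0.80 to 11.2 ± 1.43 FPKM, with a log2 change of 1.43, a standard error of 0.15 and an adjusted p of 0.0104. Ass1, which encodes an enzyme of arginine synthesis, rose from 12.8 ± 4.78 to 33.0 ± 0.33 FPKM, and Gstm6, a glutathione transferase gene, rose from 12.9 ± 0.87 to 34.2 ± 8.42 FPKM. Tnrc18, Ptprv and Palm2 rose by 1.44, 1.38 and 1.33, and Palm2 overlaps Pakap on the same strand.

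Among 28 measured granulosa cell genes, 10 fell, 3 rose and 15 did not pass. With p adjusted over the list alone, 14 fell and 7 rose. Fst, which encodes the activin-binding protein follistatin, fell from 123 ± 24.6 to 33.4 ± 8.60 FPKM (SD, n = 3; log2 change -1.85, standard error 0.20, adjusted p 0.0118). Gja1, the main gap junction gene of granulosa cells, fell from 793 ± 106 to 387 ± 24.6 FPKM, a log2 change of -1.02. Nap1l5 fell from 124 ± 34.1 to 27.1 ± 4.69 FPKM and Slc18a2 from 136 ± 6.05 to 86.6 ± 4.39 FPKM. Wt1 and Gatm were among those that rose, by 0.61 and 1.01 on the log2 scale, and were chosen for naming after their values were seen. The list was lower by camera at an adjusted p of 0.00507, with a median log2 change of -0.30, and this call was lost at an adjusted p of 0.839 with an estimated correlation.

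Of 29 measured genes of TGF-beta and BMP signalling, 2 fell and none rose; adjusted over the list alone, 2 fell and 4 rose. Grem1, a BMP antagonist gene, fell from 2.22 ± 0.87 to 0.21 ± 0.08 FPKM, and Bmpr1b, a BMP receptor gene, from 27.7 ± 3.69 to 16.6 ± 0.62 FPKM (SD, n = 3). Their log2 changes were -1.38 and -0.70, at adjusted p-values of 0.0204 and 0.024. The list as a whole did not pass, at an adjusted p of 0.52.

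Of 23 measured proliferation genes 7 fell and none rose, and 21 had a negative log2 change. There were 18 that fell when adjusted over the list alone. Top2a, a topoisomerase gene of dividing cells, fell from 80.7 ± 2.01 to 43.7 ± 3.06 FPKM (SD, n = 3; log2 change -0.87, standard error 0.08, adjusted p 0.00918). The ribonucleotide reductase gene Rrm2 fell by 0.69, the cyclin gene Ccna2 by 0.75 and the replication clamp gene Pcna by 0.49 on the log2 scale. Ccna2 overlaps Exosc9 on the opposite strand. Camera gave an adjusted p of 3.2e-13 and a median log2 change of -0.41, and the call was lost at an adjusted p of 0.669 with an estimated correlation.

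In the list for meiotic arrest and maturation, 5 of 21 measured members fell and 1 rose. Adjusted over the list alone, 10 fell and 2 rose. The members that fell with the smallest p also act in mitosis. Cks2, a partner of cyclin-dependent kinases, fell from 118 ± 1.89 to 69.7 ± 4.64 FPKM (SD, n = 3; log2 change -0.75, adjusted p 0.0103). The kinase genes Cdk1 and Aurka fell by 0.61 and 0.62 on the log2 scale, and Fbxo5, an inhibitor of the anaphase-promoting complex, by 0.47. Named after their values were seen, the cyclin gene Ccnb2 fell by 0.58 and the oocyte phosphodiesterase gene Pde3a rose by 0.59. The list was lower by camera at an adjusted p of 1.3e-05, and at an adjusted p of 0.839 with an estimated correlation.

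Among 22 measured genes for the zona pellucida and for oocyte-secreted or surface proteins, 2 rose and none fell. Zp2 rose from 241 ± 17.5 to 452 ± 72.3 FPKM and Zp3 from 277 ± 19.5 to 484 ± 117 FPKM (SD, n = 3), with log2 changes of 0.89 and 0.78 and adjusted p-values of 0.0204 and 0.0454. Both encode proteins of the coat of the egg. Adjusted over the list alone, 4 rose and 1 fell, and the list did not pass, at an adjusted p of 0.706. Of 15 measured oocyte transcription factor genes, Sohlh1 and Figla rose, and 4 rose when adjusted over the list alone. Figla, which activates the zona genes, rose from 6.59 ± 1.89 to 13.7 ± 0.81 FPKM, a log2 change of 0.98 with an adjusted p of 0.0305, while the list had an adjusted p of 0.125.

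Of 31 measured maternal-effect genes, whose products act in the early embryo, 2 rose, none fell and 24 had a positive log2 change. Padi6 rose from 305 ± 23.6 to 607 ± 153 FPKM and Khdc3 from 46.9 ± 5.06 to 74.4 ± 13.0 FPKM (SD, n = 3), at adjusted p-values of 0.038 and 0.0468; both belong to a protein complex under the surface of the egg. There were 3 that rose when adjusted over the list alone. The list was higher by camera at an adjusted p of 0.00759, and at an adjusted p of 0.839 with an estimated correlation. The adjusted p by camera moved to 0.0559 without control 1 and to 0.269 without cKO 3.

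Of 19 measured genes of the piRNA pathway and germ cell RNA granules, 3 rose and 1 fell; 6 rose and 2 fell when adjusted over the list alone. Mael, Piwil2 and Tdrd9, which act in the silencing of transposons, rose by 1.07, 0.96 and 0.78 on the log2 scale. Tex15, from the same pathway, fell from 21.3 ± 0.95 to 10.3 ± 0.59 FPKM (SD, n = 3; log2 change -0.98, standard error 0.08, adjusted p 0.00803). The list had an adjusted p of 0.062. Of 20 measured genes of meiotic prophase and synapsis, Syce1 and Smc1b rose, by 0.76 and 0.85, and 3 rose when adjusted over the list alone. Both were low, with Syce1 at 0.65 ± 0.15 FPKM in control and 1.81 ± 0.25 FPKM in cKO. That list had an adjusted p of 0.222.

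**Figure D3:**
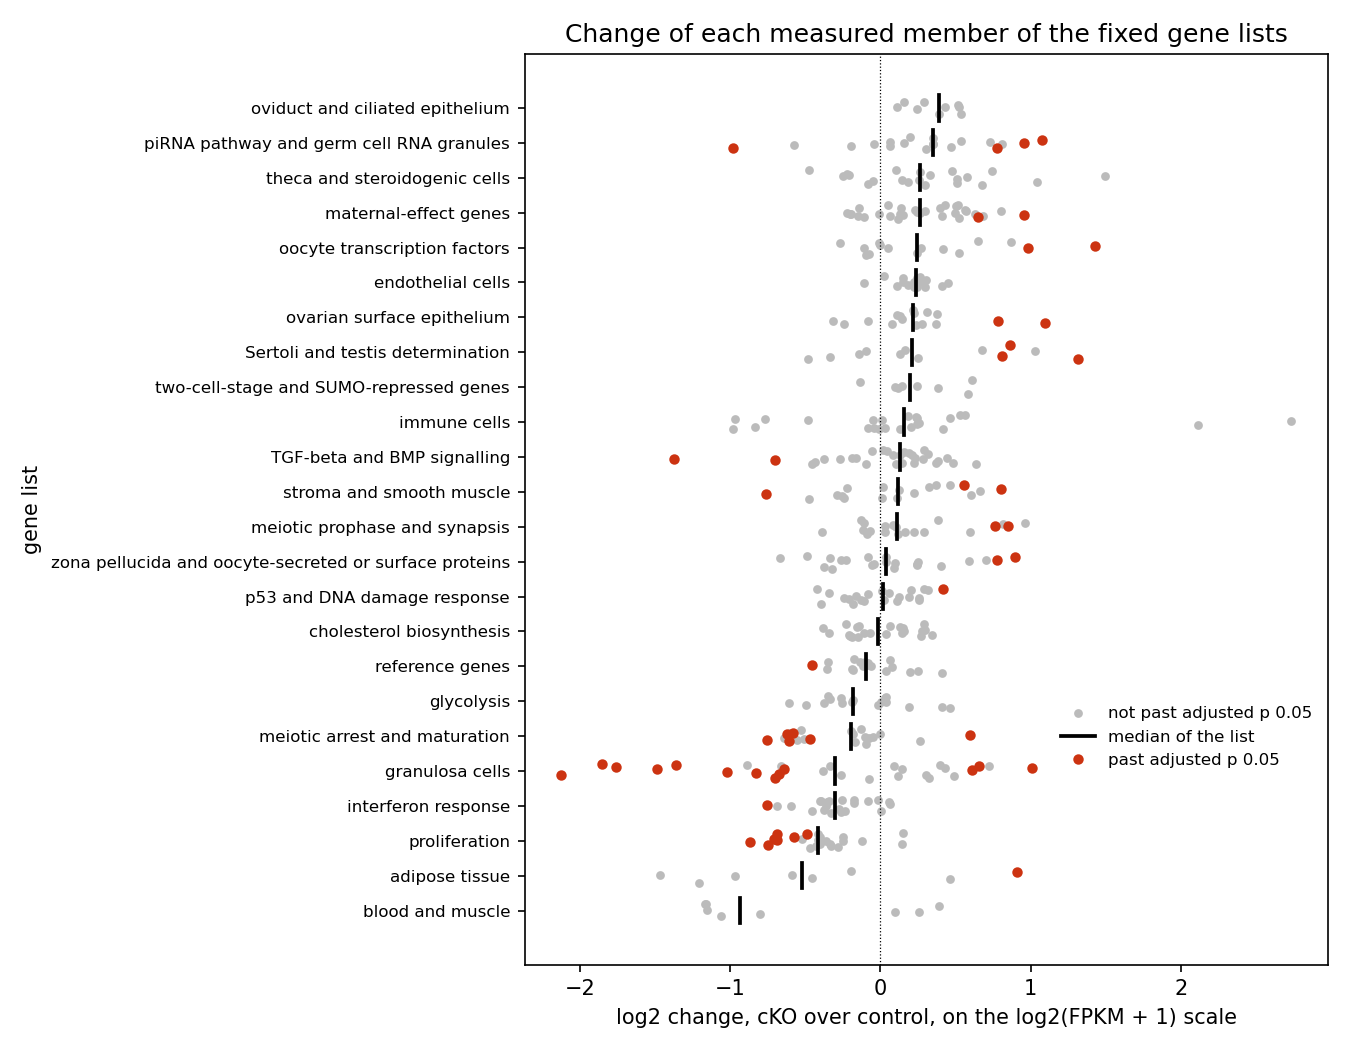
Log2 change (cKO over control, log2(FPKM + 1) scale) of every measured member of the fixed gene lists, with the SUMO pathway list left out; red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. The proliferation list has a median of -0.41 with 7 red points, all below 0, and the granulosa list has 10 red points below 0 and 3 above.

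Genes of other ovarian cell types changed in small numbers. Of 18 measured stroma and smooth muscle genes, Tcf21 and Pdgfra rose by 0.55 and 0.81 and Fbln1 fell by 0.76; adjusted over the list alone, 4 rose and 1 fell. Of 16 genes of the ovarian surface epithelium, Igfbp5 rose from 114 ± 7.22 to 249 ± 53.3 FPKM (SD, n = 3) and Bnc2 from 5.22 ± 0.38 to 9.78 ± 1.74 FPKM, the same 2 being counted adjusted over the list alone. The mean log2 level of this list was 3.35 to 3.54 in control and 3.08, 4.21 and 3.68 in cKO 1 to 3. In cKO 1, where the list was lowest, Igfbp5 and Bnc2 still read 232 and 9.52 FPKM. Of 12 Sertoli cell and testis determination genes, Gstm6, Aard and Cldn11 rose, and 5 rose and 1 fell when adjusted over the list alone. Of 21 theca and steroidogenic genes none passed; the steroid enzyme gene Hsd3b1 measured 1335 ± 168 FPKM in control and 1290 ± 149 FPKM in cKO. Of 16 endothelial genes none passed over all genes and 2 rose adjusted over the list alone, while 15 had a positive log2 change. The endothelial list was higher by camera at an adjusted p of 0.013, and at an adjusted p of 0.839 with an estimated correlation, 0.0538 without control 1 and 0.0749 without cKO 2. The lists for stroma, surface epithelium, Sertoli cells and theca had adjusted p-values of 0.479, 0.171, 0.139 and 0.291.

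Interferon response genes were lower as a list by camera at an adjusted p of 3.2e-06, and at an adjusted p of 0.669 with an estimated correlation. Of 22 measured members 1 passed. Isg15, a ubiquitin-like interferon-induced gene, fell from 6.53 ± 1.03 to 3.46 ± 0.69 FPKM (SD, n = 3; log2 change -0.76, adjusted p 0.0382). Adjusted over the list alone, 4 fell, and 19 members had a negative log2 change. In the p53 and DNA damage list 1 of 22 members passed, with Plk2 higher by 0.42, and 1 rose when adjusted over the list alone. No member passed over all genes for cholesterol biosynthesis (22 measured), glycolysis (17), immune cells (24), oviduct and ciliated epithelium (9), blood and muscle (8) and the list of 2-cell-stage and SUMO-repressed genes (8). Adjusted over the list alone, 1 cholesterol gene fell and the others had none. The adjusted p-values of these lists were 0.479, 0.102, 0.766, 0.0923, 0.156 and 0.759, and the p53 list had 0.576.

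Markers of other tissues varied between libraries of a group. The mean log2 level of the adipose tissue list was 3.17 in control 3 against 1.98 and 2.11 in the other controls and 1.92 to 2.03 in cKO. In that list Plin1, a lipid droplet gene, rose from 5.97 ± 0.94 to 12.1 ± 1.68 FPKM, and the list had an adjusted p of 0.34 by camera. Adjusted over the list alone, 2 rose and 1 fell. Of its 8 measured members 6 had a negative log2 change. Plin1 did not follow the list level, being lowest in control 3, at 4.95 FPKM. The globin gene Hba-a2 measured 1205 ± 662 FPKM in control and 603 ± 497 FPKM in cKO. The neutrophil gene S100a9 measured 307 FPKM in cKO 3 and at most 0.85 FPKM in any other library. Among 18 reference genes B2m fell, by 0.45 on the log2 scale; adjusted over the list alone, 1 rose and 2 fell, and the list had an adjusted p of 0.0966. The median log2 change was positive but camera pointed down for the SUMO, p53 and immune lists.

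By camera with its preset correlation, 6 of the 25 lists passed, and with an estimated correlation or by fry 0 passed after adjustment. At an unadjusted p, 1 list, proliferation, stayed below 0.05 with an estimated correlation, at 0.0398. Its lowest control library and its highest cKO library had mean log2 levels of 4.97 and 4.71, and the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give. This p does not set the list apart, as the granulosa, interferon and endothelial lists, among others, also had 0.1. The split by genotype gave 6 passing lists and 646 passing genes, while other splits of the 6 libraries into 3 and 3 gave up to 16 passing lists and up to 3 passing genes.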

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

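After the data were seen, 4 alternatives were chosen: GC content and length trends removed, protein-coding nuclear genes rescaled, control 3 and cKO 3 left out together, and the 3 controls against cKO 1. No paired analysis was possible because the labels give no replicate numbers, and the numbers used here only name the libraries. Count-based alternatives were not run, and the authors' own test was not analysed here.

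All 54 named genes past the threshold kept their direction under every alternative run, and so did the 646 passing genes wherever they were still tested. Their calls were less stable. Over fits with 1 library left out, which hold fewer samples, the genes that rose numbered 0 to 307 and those that fell 2 to 353, with 2266 to 3633 genes at an unadjusted p below 0.05. Low counts came from leaving out control 1 (1 higher and 4 lower), control 2 (0 and 2), cKO 1 (0 and 2) or cKO 2 (40 and 38). With no filter on low values 4 rose and 24 fell among 23854 genes, and 24 of these 28 were among the 646. Array weights gave 1041 and 743, which held 644 of the 646. A log2 change of at least 1 left 39 and 66 by construction. Centring on the median gave 254 higher and 577 lower, quantile normalisation 270 and 421, centring on the reference genes 437 and 251, removal of GC content and length trends 242 and 386, and rescaling on protein-coding nuclear genes 741 and 367. The share of higher genes went from 51.7% to between 30.6% and 63.5% with centring or quantile normalisation, and the median log2 change of all genes from 0.05 to between -0.02 and 0.12. It was 38.5% with trends removed and 66.9% on protein-coding nuclear genes, which also changed the genes tested, to 14740 and 14608. Under these 5 settings 484 to 588 of the 646 were called. Leaving out control 3 and cKO 3 gave 204 and 267, with 286 of these 471 among the 646, and the 3 controls against cKO 1 gave 22 and 1, with 2 of these 23 among them. Shared calls were 415 of 660 without control 3, 294 of 385 without cKO 3 and 65 of 78 without cKO 2. Fits with 1 library left out called from 2 genes without control 2 to 660 without control 3, so sample number alone did not set these counts. The cause of the differences between settings was not tested.

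The 6 passing lists became 0 with an estimated correlation, 10 with GC content and length trends removed, 10 without control 3 and cKO 3, and 5 to 11 with 1 library left out. Medians stay as they were with an estimated correlation, at -0.41 for proliferation, -0.30 for interferon, -0.196 for meiotic arrest, -0.30 for granulosa, 0.261 for maternal-effect and 0.23 for endothelial genes. Maternal-effect genes no longer passed at 0.182 without control 3 and cKO 3 and at 0.28 against cKO 1 alone, with medians from 0.086 to 0.39 when 1 library was left out. Endothelial genes no longer passed with array weights, at 0.20, without control 1, at 0.22, or without cKO 2, at 0.19, and ranged from 0.16 to 0.29 with 1 library left out. Granulosa genes no longer passed against cKO 1 alone, at -0.25, and ranged from -0.39 to -0.13 with 1 library left out. Proliferation genes passed under every alternative with the preset correlation. With 1 library left out, medians ranged from -0.35 to -0.17 for meiotic arrest, -0.44 to -0.37 for proliferation and -0.38 to -0.27 for interferon genes.

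Reversals were of results that did not pass in the planned fit. Hsd3b1 went to 0.12 with quantile normalisation, 0.021 with reference centring, 0.030 with array weights, 0.020 on protein-coding nuclear genes, 0.072 without control 3 and cKO 3, 0.13 against cKO 1 alone and between -0.14 and 0.052 with 1 library left out. Aldoa went to -0.031 with median centring, -0.024 with GC content and length trends removed, -0.052 without control 3 and cKO 3 and between -0.057 and 0.16 with 1 library left out. S100a8 ranged from -0.48 without cKO 3 to 3.41, and read -0.58 without control 3 and cKO 3 and -0.48 against cKO 1 alone. Egfl7 read -0.10 against cKO 1 alone. Of the list tests whose direction by camera turned, median log2 changes follow. The SUMO list read 0.011 at a mean FPKM of at least 2, 0.027 with quantile normalisation, 0.082 with reference centring, 0.017 with array weights, 0.079 on protein-coding nuclear genes, 0.093 against cKO 1 alone and -0.013 to 0.054 with 1 library left out. The zona and oocyte-secreted list read -0.036 without control 3 and cKO 3, -0.12 against cKO 1 alone and -0.088 to 0.14 with 1 library left out. With 1 library left out, the list of 2-cell-stage and SUMO-repressed genes ranged from -0.11 to 0.76, TGF-beta and BMP signalling from 0.065 to 0.14, immune cells from 0.0001 to 0.22 and ovarian surface epithelium from -0.13 to 0.55. TGF-beta and BMP signalling read 0.11 without control 3 and cKO 3, and cholesterol synthesis 0.054 against cKO 1 alone. Immune cells read 0.090 with median centring and 0.14 with GC content and length trends removed, and the reference genes 0.022 with quantile normalisation. Ovarian surface epithelium read -0.44 against cKO 1 alone, at an adjusted p of 0.00209, against 1.2e-05 to 0.839 over all alternatives; the cause was not tested. Depth limits the low genes: an FPKM of 1 in a gene of 2 kb stands for 39.2 to 49.8 estimated fragments.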

Other observations

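Tests of a granulosa cell share, of a common factor and of dilution in the scaling, of trapped blood and of a mislabelled control were chosen after the results they bear on were seen, as were the genes and groups in this part, the removal of GC content and length trends and the axis used for library positions.

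Mast cell genes rose beyond the 4 among the largest increases. Of 9 measured mast cell genes 5 rose and all 9 had a positive log2 change; Cma1, the chymase gene, rose from 3.33 ± 0.57 to 8.45 ± 2.29 FPKM (SD, n = 3; adjusted p 0.0332). Hdc, which makes histamine, had a log2 change of 0.31 at an adjusted p of 0.292. Among mast cell genes whose values had not been looked at, only Srgn was measured, with a log2 change of 0.082 and an adjusted p of 0.808. Several imprinted genes that are high in fetal tissue rose as well. Peg10 rose from 16.0 ± 2.64 to 36.2 ± 3.50 FPKM (adjusted p 0.0119), H19 from 34.0 ± 4.26 to 63.3 ± 12.7 FPKM and Igf2 from 10.6 ± 2.38 to 18.3 ± 0.27 FPKM, and Peg3 rose by 0.78 on the log2 scale. Of 21 measured imprinted genes 4 rose and 2, Mest and Nnat, fell. The 17 whose values had not been looked at gave a camera p of 0.324, unadjusted, with a median log2 change of 0.16, and a p of 0.348 with an estimated correlation.

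Gm11223, a processed pseudogene on chromosome 4 from 69925630 to 69926079 (mm10), lies outside the naming rule and had the largest log2 decrease of the passing genes: 27.4 ± 2.11 FPKM in control and 0.26 ± 0.41 FPKM in cKO (SD, n = 3; log2 change -4.54, adjusted p 6.5e-04). AC124080.2, a clone-named gene on chromosome X from 89849394 to 89849503 annotated as a microRNA gene, had the largest increase, from 65.8 ± 17.1 to 345 ± 78.8 FPKM (log2 change 2.38, adjusted p 0.00995). The annotated span of AC124080.2 is shorter than the fragment length assumed in the depth estimate. The length behind its FPKM is not known, so the value cannot be read as a microRNA level. Bmp15, an oocyte growth factor gene, measured 47.2 ± 16.0 FPKM in control and 31.4 ± 17.0 FPKM in cKO, at an adjusted p of 0.381. Cyp17a1, an enzyme gene of theca cells, read 145 FPKM in control 1 against 24.3 and 14.1 FPKM in control 2 and control 3, and 113, 184 and 58.0 FPKM in cKO 1 to 3. The 38 measured microRNA genes had a median log2 change of 1.22, with 1 of them past the threshold. Much of this came from cKO 1: relative to the mean of each gene over the libraries, their median was 1.423 in cKO 1, 0.108 in cKO 2 and -0.49 in cKO 3, and -0.703 to -0.498 in the controls. Whether the FPKM of these genes reflects microRNA levels was not tested.

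With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The split by genotype was the 1 split with as many higher genes, 334 against at most 2 in 1 direction in the others, and likewise the 1 split with as many lower genes, 312 against at most 2. For lists, 8 of the 10 splits gave as many as the 6 of the genotype split, and the highest other split gave 16.

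The 17 granulosa and proliferation genes that fell had a median log2 change of -0.75. A lower share of granulosa cells, or dilution by RNA of other cells, would lower all of their genes, yet 3 measured granulosa genes, Wt1 and Gatm among them, rose past the threshold, which argues against either as the whole cause. Before this, 2 tests of dilution were tried that decide nothing: the median centred on reference genes, -0.68, as other cells express these too, and the 53.6% of 28 granulosa genes more than 2 standard errors above -0.75, a level set by genes picked because they fell. With GC content and length trends removed the median was -0.757, and the median of all genes, which a common factor from the scaling would lower, was 0.046, so neither accounts for the pattern. Altered expression within granulosa cells, a different mix of follicle stages and fewer dividing cells may each be involved and were not tested, and the genotype, the difference the design names, stays open as well.

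In cKO 3 the neutrophil genes S100a8, S100a9 and Retnlg measured 219, 307 and 50.3 FPKM, and at most 0.85 FPKM in any other library. Trapped peripheral blood would bring globin too: Hba-a1 was 985 FPKM in cKO 3 against 346 and 187 FPKM in the other cKO libraries, and the blood and muscle list was highest in cKO 3, at a mean log2 level of 6.137 against at most 6.05 elsewhere. Yet Hba-a1 in cKO 3 was 0.632 times its highest control value, 1557 FPKM in control 1, where S100a8 read 0.59 FPKM. In control 2 Hba-a1 read 957 FPKM and S100a8 0.41 FPKM, so globin at such levels came with little S100a8 in these controls. The globin values thus point both ways, and blood stays open as a source. Of 13 neutrophil genes whose values had not been looked at, 84.6% were at least 2-fold higher in cKO 3 than in the next library, among them Lcn2 at 19.8 FPKM and Ly6g at 2.10 FPKM. This is consistent with neutrophils in at least 1 of the ovaries pooled for cKO 3, and a pattern in 1 library gives no link to the genotype.

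Control 3 lay at 0.411 on the axis from the other controls to cKO, with quartiles over genes of 0.239 and 0.612. Its quartiles overlap those of cKO 3, 0.478 and 0.832, and of cKO 2, 0.499 and 1.098, so they do not decide on a cKO pool labelled as control. Single genes, picked after their values were seen, went both ways. Gm11223 read 25.2 FPKM in control 3, 27.6 and 29.4 FPKM in control 1 and control 2, and at most 0.74 FPKM in cKO. Sycp3 read 10.3 FPKM in control 3, 2.97 and 3.05 FPKM in control 1 and control 2, and 7.28 to 11.9 FPKM in cKO. In a further test control 3 lay below 0.25 at 26.8% of the 500 genes picked without it. The share was at most 10.8% for a cKO library and at least 80.4% for the other controls. This test cannot decide, since the quartiles already seen largely set its outcome. Each library also had its own genes and axis, and the axes of the cKO libraries included control 3 in their zero point. Lower depth, at 19.6 M fragments, would matter less in high genes, but the position was 0.399 among the 182 genes with a mean of at least 20 FPKM. A pool in which 1 of 3 ovaries was cKO may be considered too. Stage or dissection differences between pools were not tested; the adipose list was also highest in control 3.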
